A study of Mus musculus with 2 samples.

How the data were processed

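Total RNA from 2 single neonatal mouse hearts (postnatal day 0, strain B6NCrl, littermate pups 2 and 3) was profiled by sequencing. Per the labels, RNA was extracted with the Ambion mirVana kit, 10 ng went into each library, spike-in RNAs were added, the size range was above 200 bases, and the manual of a SMARTer Ultra Low kit is listed among the protocols. Whether that kit keeps strand information in the counts is not given in the sources used here, so reads of a gene and of its antisense partner, such as Xist and Tsix, cannot be told apart.

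The authors deposited a gene table and a transcript table for each library, with no pooling of libraries. Per the deposited read-me, values were quantified on mm10 with the GENCODE M4 annotation; the column names are those of RSEM output, and the aligner and tool versions are not given in the sources used here. Expected counts, per the file headers, are estimated reads per feature in which the authors' processing shared out reads that match several features. TPM values, per the file headers, are expected counts divided by effective length and scaled to a fixed total over all features, including spike-ins and mitochondrial genes. FPKM values, per the file headers, are scaled by effective length and total reads. The deposited tables also give posterior means, the posterior SD of the count and the bounds of credibility intervals of TPM (a signal in TPM units) whose width is not stated in the files. The deposited percent column of the transcript table is each transcript's share of its gene. The deposited effective length equals length minus 99 bases.

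The gene table held 69691 features, of which 43346 were Ensembl genes, 96 ERCC spike-ins and 26248 features named by a number. Of the Ensembl genes, 42462 were matched by identifier to the GENCODE M21 annotation of the same genome build, which supplied symbols, biotypes and coordinates. The unmatched genes held 0.117% and 0.116% of counts. Gene lists used 5 symbols through synonyms, and 6 symbols had no match.

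Libraries held 46151722 and 44707283 expected counts, the total behind every count here. For a gene of median length, 3 counts corresponded to 0.0752 and 0.0760 TPM. A gene was called detected at 1 TPM or more. Reads were called shared where the posterior SD of the count exceeded 10% of its posterior mean in either library, and pseudogenes with at least 50% of 31-base words shared with mitochondrial genes were treated as nuclear copies.

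Before the data were examined, 40 gene lists, 43 gene pairs, the tests and the alternatives were fixed. The genes named were, by rule, the 25 most abundant nuclear-encoded genes, the 4 most abundant detected members of each list, both members of each pair, the 10 genes with the most positive and the 10 with the most negative ratio between the pups among those counted as differing, sex-linked genes, and of the genes with regulated splicing the 10 most abundant and any whose main transcript differed. Genes named outside this rule were chosen after their values were seen: Alas2, Slc4a1, Isg15, Oasl2, Mcm7, Ager, Sec14l3, Angptl4, Spp1, Mmp12, Car3, Shox2, mt-Co2, mt-Co3, mt-Nd4l, Gm10925, Gm28439 and those of the closing part. Pairs were compared as the log2 ratio of TPM + 1 within each pup. The result of 1 contractile pair, included in the counts of pairs, is not reported by name. The biological coefficient of variation was estimated with edgeR 4.0.16 (R 4.3.3) on expected counts rounded to whole numbers, with TMM scaling, filterByExpr and an intercept-only design. Differences between the pups were log2 ratios of TMM-scaled counts with a prior count of 2, replicate 2 minus replicate 1. Lists used genes with a mean count of 20 or more, and their median was placed among 10000 random lists drawn from 20 bins of mean count. Below 2.5 or above 97.5 a list was said to stand apart. Random lists matched on length or GC content were instead drawn from 20 bins of mean TPM, each split into 10 by that property. Single genes were counted as differing at a mean count of 50 or more and an absolute log2 ratio of 1 or more. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

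On simulated data, biological coefficients of variation of 0.05, 0.1 and 0.2 were returned as 0.0512, 0.0997 and 0.199 over 15980 genes. Among simulated genes, 0.0151% of 13263 unchanged ones were counted as differing, against 100% of 50 genes at a log2 ratio of 1.5, 100% of 50 at 2.5, 98% of 50 at -1.5 and 0% of 50 at 0.5. Every simulated gene had the same coefficient of variation, 0.0892, and no shared reads. The 0.0151% thus does not carry over to real genes with a wider spread or shared reads. Of 100 simulated lists of 25 genes, 1% stood apart above with no shift, 17% at a shift of 0.05, 52% at 0.1 and 97% at 0.2.

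Alternatives were DESeq2 1.42.0 size factors, scaling by the spike-ins, TPM ratios, FPKM, posterior means, unscaled counts, other pseudocounts and filters, and each replicate left out. Against TMM, DESeq2 size factors moved the median ratio of all genes by -0.02 and the spike-ins by 0.06. Spike-in concentrations were not used here.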

Results

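Total RNA was sequenced from the hearts of 2 mouse pups of the inbred strain B6NCrl, taken on postnatal day 0. The labels describe replicate 1 as the single heart of pup 2 and replicate 2 as that of pup 3, both of pregnancy 1. Both samples carry the same donor identifier, and they were treated as 2 animals on the strength of these descriptions. There was 1 group, neonatal heart (n = 2), with no other age, tissue or treatment, so the comparisons that follow are between genes within the hearts and between the littermates. The purpose of the series was not stated in its labels. The libraries held 46151722 (replicate 1) and 44707283 (replicate 2) expected counts. A count of 3, the most that chance could leave at 0, corresponded to 0.0752 and 0.0760 TPM (transcript abundance scaled by length and depth) for a gene of median length. Such floors cover counting error only, and no interval given here measures the spread between animals. Values are in TPM, given as the mean ± SD of the pups unless stated, and coordinates are on mm10.

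Genes of the contractile apparatus and of mitochondrial energy metabolism dominated the neonatal heart. Actc1, the cardiac actin gene (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548), was the most abundant protein-coding nuclear gene, at 15157 ± 1775 TPM. It was followed by Myl2, the ventricular regulatory myosin light chain (chromosome 5, 122100951 to 122113472), at 11771 ± 66.7 TPM. Tnnt2, cardiac troponin T (chromosome 1, 135836354 to 135852260), reached 10319.7 ± 492 TPM, and Fabp3, the heart fatty acid binding protein, 8502 ± 511 TPM. Tpm1, which encodes tropomyosin, stood at 7702 ± 154 TPM, Nppa, the atrial natriuretic peptide gene, at 7492 ± 289 TPM, and Tnni3, cardiac troponin I, at 6814 TPM in replicate 1 and 6840.5 TPM in replicate 2.

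The 37 genes of the mitochondrial chromosome took 13.1% ± 0.0379 of all TPM. The most abundant were mt-Atp6 (26353 ± 66.6 TPM), mt-Atp8 (21506 ± 56.0 TPM) and mt-Rnr2 (16383 ± 109 TPM). Another 5.57% ± 0.102 lay in 7 pseudogenes clustered on chromosome 1, among them Gm28437 (24613189 to 24613971, 26372 ± 1200 TPM) and Gm29216 (24615706 to 24616197, 13855 ± 480 TPM). These share at least 50% of their 31-base sequences with mitochondrial genes, and reads were shared for mt-Atp6, mt-Co2, mt-Co3 and mt-Nd4l and for Gm28437, Gm28661, Gm10925 and Gm28439 among the copies, whose levels are uncertain. The counts of Gm29216 and Gm28438 had a posterior SD under 10% of their mean. That does not show whether the RNA came from the nuclear copies or from the mitochondrial chromosome. The sum over the mitochondrial chromosome and the copies was 18.7% ± 0.0642. Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA, together took 1.55% ± 0.0315, and the 11 haemoglobin genes 1.13% ± 0.351. The 10, 50 and 100 most abundant genes held 16.4% ± 0.0369, 36.6% ± 0.226 and 46.4% ± 0.145 of TPM. At 1 TPM or more, 13121 genes were detected in replicate 1 and 13162 in replicate 2. Both pups shared 12812 of them, 11699 of which are protein coding.

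Adult or ventricular contractile forms exceeded their fetal, atrial or skeletal partners in most of the pairs fixed beforehand. Myh6, the fast alpha myosin heavy chain that prevails in the adult mouse heart (chromosome 14, 54941921 to 54966927), stood at 3487 ± 542 TPM against 494 ± 160 TPM for Myh7, the slow beta chain (54970684 to 54994626). The ratio of the means was 7.05. Tnni3 was 2.05-fold above Tnni1, the slow skeletal troponin I of the fetal heart (3324 ± 8.48 TPM). Actc1 was 149-fold above the skeletal actin gene Acta1 (102 ± 16.0 TPM). Among chamber forms, Myl2 was 2.72-fold above the atrial light chain Myl7 (4323 ± 719 TPM), and Myl3 6.26-fold above Myl4 (969.9 ± 94.0 TPM). Wide gaps also lay between Tnnt2 and Tnnt1 (137-fold), Tpm1 and Tpm2 (94.1-fold) and Mybpc3 and Mybpc2 (450.05-fold), of which Mybpc3 is the cardiac myosin binding protein. Tnnc2 was near 0 (0.160 ± 0.0424 TPM, with shared reads) beside 5851 ± 13.1 TPM of Tnnc1.

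Pln, which restrains the sarcoplasmic calcium pump, was 2.01-fold above its atrial relative Sln (833 ± 142 TPM). The gap junction gene Gja1 was 8.42-fold above Gja5, the calcium store gene Casq2 13.3-fold above Casq1, and Camk2d 39.98-fold above Camk2b. Cacna1c, the pore of the L-type calcium channel, was 14.9-fold above the T-type channel gene Cacna1h, but 75.4% of its TPM lay in a processed transcript of 954 bases and 15.4% in a coding one of 13162 bases. The second form was higher in 2 pairs. In one of them Nppb, the ventricular natriuretic peptide gene, stood at 251 ± 154 TPM against 7492 ± 289 TPM for Nppa. The pacemaker channel genes Hcn2 and Hcn4 were both under 1 TPM and the pair was not called. Of 17 contractile pairs, 14 thus had the first form higher.

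Among 17 metabolic pairs the muscle form was higher in 13. Slc2a4, the insulin-responsive glucose transporter, stood at 67.8 ± 0.0141 TPM against 15.6 ± 0.453 TPM for Slc2a1. Pgam2 was 8.25-fold above Pgam1, Ckm 10.6-fold above Ckb, Cpt1b 8.85-fold above Cpt1a and Fabp3 21.3-fold above Fabp5. Cpt1b and Cpt1a encode the enzyme that admits fatty acids to mitochondria. Slc25a4 exceeded Slc25a5 3.73-fold, Pfkm exceeded Pfkl 3.19-fold and Acacb exceeded Acaca 6.03-fold. Gys1 stood at 52.6 ± 1.29 TPM, with Gys2 at 0 counts in replicate 1 and 3 in replicate 2. Ppargc1a was 1.95-fold above Ppargc1b. Smaller gaps were found for Cox6a2 over Cox6a1 (1.71-fold), Ldhb over Ldha (1.34-fold) and Eno3 over Eno1 (1.16-fold). The last turned to a log2 ratio of -0.07 on counts not divided by length.

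The other form was higher in 3 metabolic pairs. Hk2 stood at 22.3 ± 0.346 TPM against 105.5 ± 11.2 TPM for Hk1. Cox7a1 (1146 ± 46.3 TPM) was below Cox7a2 (1583 ± 67.6 TPM), and Cox8b (1403 ± 12.0 TPM) below Cox8a (2319 ± 6.87 TPM). Pdk4 and Pdk3, which encode kinases that inhibit pyruvate dehydrogenase, were not separated. Their log2 ratio was 0.32 ± 0.64 and differed in sign between the pups, with Pdk4 at 75.1 ± 30.1 TPM.

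In signalling and other genes, Igf2 and the thyroid receptor gene Thra prevailed over their partners, while haemoglobin was of the adult type. Igf2, the fetal growth factor, stood at 749 ± 50.9 TPM against 18.8 ± 1.79 TPM for Igf1. Thra stood at 32.2 ± 1.85 TPM against 0.455 ± 0.00707 TPM for Thrb. Hbb-bs reached 2879 ± 850 TPM, with its embryonic partner Hbb-y at 1.78 ± 0.255 TPM, and Hba-a1 reached 2063 ± 637 TPM, with Hba-x at 0.410 ± 0.156 TPM. Vegfb was 37.6-fold above Vegfa, Lmna 4.50-fold above Lmnb1, Mef2a 3.19-fold above Mef2c and Ccnd2 1.40-fold above Ccnd1. Col3a1 (463 ± 14.7 TPM) exceeded Col1a1 (257 ± 4.97 TPM). Over all 43 pairs, 33 had the first form higher, 8 the second, and 2 were not called. A call needed one sign in both pups, a mean log2 ratio larger than the difference between the pups and credibility intervals of TPM that did not overlap. No p-value is given, because an exact sign-flip test of 2 pups cannot go below a two-sided p of 0.5.

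**Figure D1:**
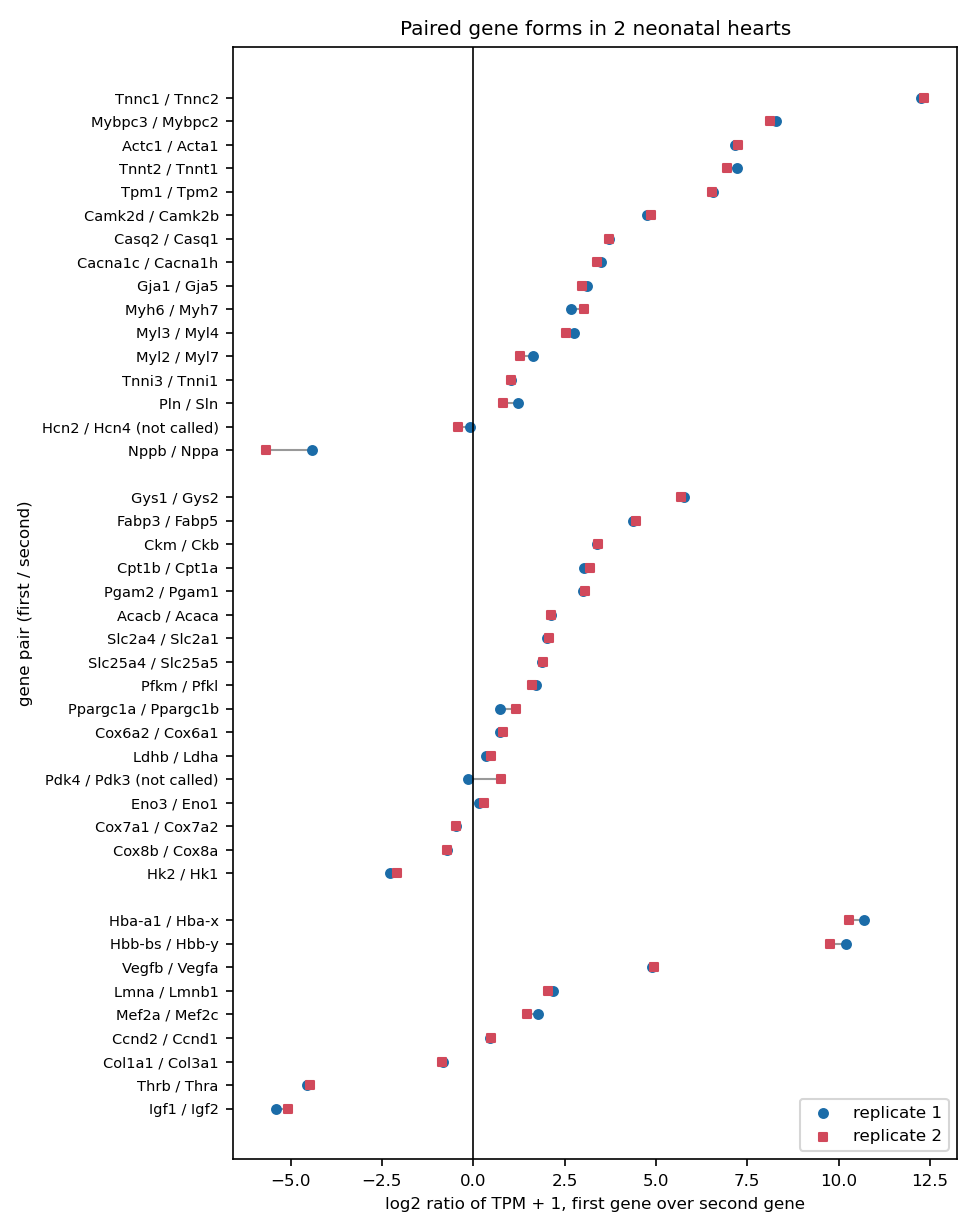
Log2 ratio of TPM + 1 (horizontal axis) of the first over the second gene of each pair shown, with 1 circle for replicate 1, 1 square for replicate 2 and a line joining them. Blocks from the top hold contractile, metabolic and signalling and other pairs, 1 contractile pair is left out, and Nppb over Nppa and Pdk4 over Pdk3 show the widest gaps between the pups.

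Heart muscle genes were detected almost completely, apart from those of the conduction system. Of the sarcomere and Z disc list 38 of 40 genes reached 1 TPM in both pups, with a summed level of 85552 ± 2792 TPM. All 16 atrial genes and all 11 ventricular genes were detected, summing to 17334 ± 130 and 20753 ± 316 TPM, the former led by Nppa and the latter by Myl2. Of the calcium handling and excitation genes 42 of 46 were detected, led by Pln (1671 ± 54.9 TPM), and Atp2a2, the sarcoplasmic calcium pump, stood at 538 ± 41.5 TPM. The conduction system list was low, with 14 of 20 genes detected and a median of 3.45 TPM. Its most abundant members were the gap junction gene Gjc1 (31.8 ± 1.01 TPM) and the transcription factor gene Irx3 (20.7 ± 0.410 TPM). Of 60 cardiac transcription factor genes and their partners, 51 were detected. Ankrd1 (460.5 ± 100.3 TPM) was the most abundant, and Nkx2-5, an early cardiac regulator, stood at 105.8 TPM in replicate 1 and 117 TPM in replicate 2.

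Markers of the other resident cell types were present as well. All 32 endothelial genes were detected, led by the lipid carrier gene Fabp4 and by Cd36, and summed to 2446 ± 6.87 TPM. All 26 fibroblast genes were detected, summing to 3098 ± 122 TPM, with Vim at 543 and 532 TPM in replicates 1 and 2. Of the endocardial and valve list 14 of 19 genes were detected, led by the matrix gene Postn (266 ± 17.2 TPM), and of the epicardial list 16 of 17, led by Msln (40.8 and 38.8 TPM). Smooth muscle and pericyte genes (20 of 21 detected) were led by Acta2, at 1130 and 884 TPM. Of 25 macrophage genes 20 were detected, led by Pf4 (49.6 ± 3.36 TPM) and Lyz2 (45.9 ± 3.69 TPM). Collagen and matrix genes numbered 45 detected of 48 and summed to 4234 ± 36.9 TPM.

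Fewer members were detected in lists of blood, nerve, fat and other tissues. Detected were 4 of 24 lymphocyte and thymus genes, 3 of 15 liver genes, 5 of 16 cartilage and bone genes, 8 of 22 neuron and Schwann cell genes and 11 of 19 neutrophil, mast cell and platelet genes. Of 26 skeletal muscle genes 9 were detected, and the 3 most abundant, Mb, Ckm and Eno3, are also heart genes. Brown and white adipocyte genes (11 of 20 detected) were likewise led by Cox8b and Fabp4, which belong to other lists here. Of 25 erythroid genes 12 were detected, with Hba-a2 at 6299 TPM in replicate 1 and 3996 TPM in replicate 2. Of 15 lung epithelial genes 3 reached 1 TPM in both pups, namely Hopx (31.2 and 32.2 TPM), Abca3 (3.24 and 2.43 TPM) and Scgb3a2, which differed widely (2.96 and 563 TPM). Hopx also belongs to the cardiac transcription factor list.

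Genes of S phase and of mitosis were detected in full. All 33 S phase genes and all 35 G2 and M phase genes reached 1 TPM in both pups, with summed levels of 653 ± 36.4 and 929 ± 30.8 TPM. Rrm2, a subunit of ribonucleotide reductase, stood at 65.3 ± 4.31 TPM, Pcna at 59.5 ± 3.79 TPM and Cdk1, the mitotic kinase, at 89.3 ± 4.12 TPM. Of 26 cell cycle inhibitors and regulators 21 were detected, led by Cdk4 (293 and 282 TPM). Of 29 replication-dependent histone genes 19 were detected, led by Hist1h2bc (122 and 148 TPM), and 16 of the 29 had shared reads.

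Energy metabolism lists were detected nearly in full. The 59 nuclear genes of oxidative phosphorylation had a median of 1416 TPM and summed to 105325 ± 2083 TPM, led by Atp5b (7402 and 7362 TPM), a subunit of ATP synthase. The 15 mitochondrially encoded genes summed to 131226 ± 379 TPM. All 38 genes of fatty acid oxidation and ketone use were detected (20455 ± 804 TPM), as were 28 of 29 glycolysis genes (15278 ± 390 TPM) and all 20 genes of the citric acid cycle (14180.1 ± 94.1 TPM). Gapdh led glycolysis at 3106 and 2833 TPM, and Mdh1 led the citric acid cycle at 2296 ± 11.6 TPM. All 61 ribosomal protein genes were detected, with a median of 366 TPM.

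Among regulatory lists, 21 of 28 imprinted genes were detected, led by Gnas (959.8 ± 5.20 TPM), Igf2 and Mest (520.2 ± 1.61 TPM). Of 46 hormone and growth signalling genes 35 were detected, with Nppa the most abundant. Detected as well were 19 of 20 hypoxia response genes, 16 of 20 interferon response genes and 28 of 32 immediate early and stress genes. The small heat shock gene Hspb1 (794 and 741 TPM) led the stress list. Of 32 long and structural non-coding RNA genes 24 were detected. Malat1, a nuclear long non-coding RNA, stood at 6820.2 ± 192 TPM and H19, an imprinted RNA, at 243 ± 6.58 TPM. Only 3 of 22 small and spliceosomal RNA genes reached 1 TPM, in libraries whose RNA was size-selected above 200 bases according to the labels. Of these, Rnu5g did so on 1 count in each pup (1.54 and 1.56 TPM), below the floor of 3 counts. A gene this short can thus pass 1 TPM on a single read.

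Of the sex-linked list, Xist, the RNA that coats the inactive X chromosome (X chromosome, 103460366 to 103483254), stood at 11.8 TPM in replicate 1 and 10.6 TPM in replicate 2. Its antisense partner Tsix stood at 9.00 and 11.2 TPM, and the 2 cannot be separated because the sources do not state whether counting used strand. All 8 Y-linked genes of the list, Kdm5d, Uty, Ddx3y, Eif2s3y, Usp9y, Zfy1, Zfy2 and Sry, had 0 counts in both pups. The 1569 annotated Y genes together held 9 and 6.45 counts, spread over 5 genes. The labels record sex as not collected. The X-linked partners Ddx3x (8602 and 5887 counts) and Eif2s3x (5058 and 4370 counts) were well expressed. With them, the 0 counts over all 8 Y-linked genes argue against a male heart in either library.

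The most abundant transcript of a gene was the same in both pups for 6095 of 6445 genes with at least 5 TPM and more than 1 transcript (94.6%, 95% Wilson interval 94.0 to 95.1%). That interval treats the genes as independent trials, which they are not, and measures no spread between animals. Among the fixed list of genes with regulated splicing, 44 of 51 could be examined and 43 had the same main transcript. Tpm1-205 carried 95.6% ± 0.358 of Tpm1, Atp2a2-202 95.1% ± 0.275 of Atp2a2, and Pkm-202 86.8% ± 1.68 of the pyruvate kinase gene Pkm, with Pkm-201 at 13.2%. Tnnt2 was divided between a main transcript of 1097 bases (45.6% ± 1.86) and another of 1112 bases (28.5%). Ttn-215, a transcript of 2159 bases, took 80.8% ± 0.532 of the TPM of the titin gene, whereas Ttn-201, of 81843 bases, took 6.64%. TPM is divided by effective length, so each read weighs more in a short transcript and these are not shares of reads. Numa1 was the exception, with Numa1-201 at 53.9% in replicate 1 and 49.8% in replicate 2, where Numa1-202 led. In 35 of the 44 genes the credibility intervals of the first and second transcripts did not overlap in either pup.

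**Figure D2:**
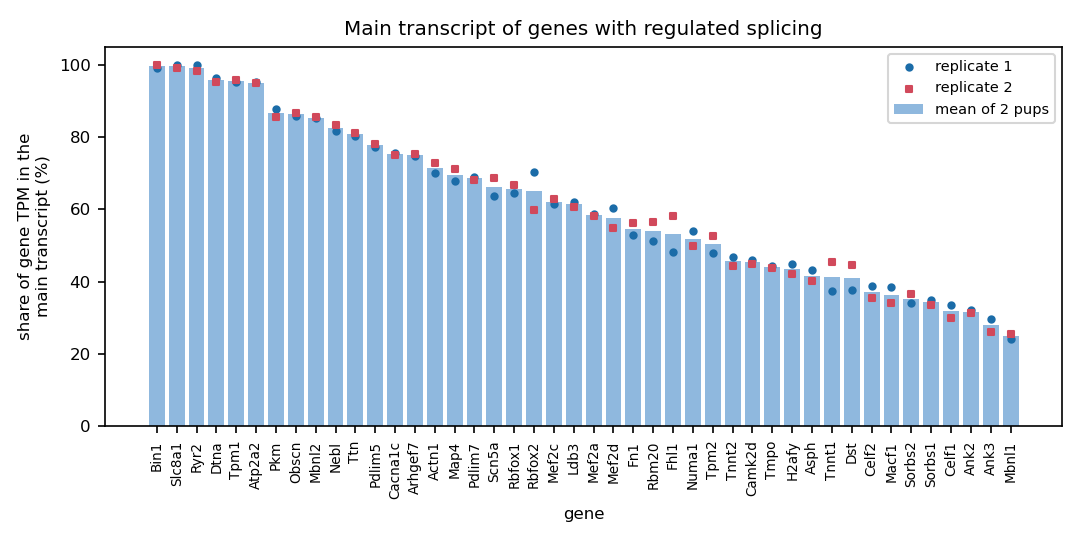
Share of a gene's TPM (percent, vertical axis from 0) in its most abundant transcript for the 44 examined genes with regulated splicing. Bars give the mean of the 2 pups, circles replicate 1 and squares replicate 2; for Tpm1 both points lie near 95.6% and for Tnnt2 near 45.6%.

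The littermates were close in expression, with a spread beyond counting error. Pearson's r of log2(TPM + 1) was 0.989 and Spearman's rho 0.988 across 13471 genes, which are not independent replicates. The biological coefficient of variation, from the common dispersion over 15980 genes, was 0.0892. Of 13463 genes with a mean count of 50 or more, 84.8% lay within 1.2-fold between the pups. The chi-square statistic of the counts was 13.7 per degree of freedom over 18163 genes. That statistic sets aside counting error only, so it does not separate the hearts from their library preparations. ERCC spike-ins, synthetic RNAs added before library preparation, drew 262 and 246 counts (0.000568% and 0.000550%). Of 96 sequences, 22 and 18 had a count and 15 had a count in both libraries. Their log2 counts gave r = 0.860 and rho = 0.755 across the 25 spike-ins seen in either library, again without a p-value, since they are not replicates.

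Red blood cell and interferon response genes were lower in replicate 2, and S phase, fibroblast and macrophage genes higher. All 18 erythroid genes with a mean count of at least 20 were lower in replicate 2, with a median log2 ratio of -0.48 (percentile 0 among 10000 random lists matched on expression). Haemoglobin genes took 1.38% of TPM in replicate 1 and 0.881% in replicate 2. Alas2, the first enzyme of haem synthesis in red cells, had a log2 ratio of -0.70 and Slc4a1, the red cell anion exchanger, -1.27. Interferon response genes were lower in 17 of 18 cases, with a median of -0.33 (percentile 0). Isg15 (-0.62) and Oasl2 (-0.49) were among them, whereas Bst2 (-0.01) and Ifi27 (-0.05), the most abundant members, were nearly equal in the pups.

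Also lower in replicate 2 were the lists of calcium handling and excitation (median -0.08, percentile 0, 32 of 45 genes lower), sarcomere and Z disc (-0.05, percentile 0.09, 25 of 40 lower, but -0.02 and percentile 3.08 at a mean count of 100 or more) and glycolysis (-0.04, percentile 1.28, 18 of 29 lower). Scaling by the spike-ins, which drew few counts, raised ratios by 0.06, more than the sarcomere and glycolysis medians lay below 0. That shift rests on 262 spike-in counts in replicate 1 and 246 in replicate 2. It cannot decide whether these 2 lists were lower in absolute terms, and they are called lower only relative to other genes. Higher in replicate 2 were all 33 S phase genes (median 0.13, percentile 100), with Mcm7 at 0.20 and Pcna at 0.13, while the G2 and M phase list did not stand apart (-0.03, percentile 18.9). Fibroblast genes (median 0.10, 19 of 26 higher, percentile 100), macrophage genes (0.13, 21 of 24, percentile 99.3), endocardial and valve genes (0.12, 12 of 19, percentile 99.6) and conduction system genes (0.14, 14 of 19, percentile 99.4) were higher as well. The conduction system list no longer stood apart at a mean count of 100 or more (0.10, percentile 97.05) or on TPM ratios (0.08, percentile 97.4). Also higher in replicate 2 were ribosomal proteins (0.07, 56 of 61, percentile 100), nuclear oxidative phosphorylation (0.06, 50 of 59, percentile 100) and neuron and Schwann cell genes (0.26, 12 of 15, percentile 99.5), the last with a bootstrap SD of 0.28 and no longer apart at a mean count of 100 or more (0.15, percentile 94.9). Cell cycle inhibitors and regulators (0.06, percentile 97.6) and fatty acid oxidation (0.04, percentile 97.53) were just past the limit.

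Of 39 lists with 5 or more such genes, 16 stood apart, 11 higher and 5 lower, against 1.95 that chance would give for independent genes. Genes of a list vary together, so this count overstates what 39 independent draws would show. Atrial (0.02) and ventricular (0.00) lists did not stand apart, nor did endothelium (-0.01), collagen and matrix (0.00) or the mitochondrially encoded genes (0.00). With 1 animal on each side, no p-value is given. The log2 ratio fell with transcript length across 15161 genes (Spearman's rho -0.197), a trend that is aligned with the direction of the ribosomal protein, oxidative phosphorylation and calcium handling lists. Matched on mean TPM and length, glycolysis (percentile 2.99) and oxidative phosphorylation (70.6) no longer stood apart. The epicardial, liver, mitochondrially encoded, collagen, and immediate early and stress lists then did. Matched on mean TPM and GC content instead, cell cycle inhibitors and regulators (94.8) and fatty acid oxidation (76.05) no longer stood apart. The lymphocyte, neutrophil, liver, mitochondrially encoded and citric acid cycle lists then did. The first random lists had been matched on mean count, so these losses and gains cannot be credited to length or GC content alone. With medians moved 1 bootstrap SD nearer to the matched lists, a requirement set after the percentiles were seen, the erythroid, interferon, S phase and lung epithelium lists stayed apart under both matchings. Fibroblast genes then failed on GC content (93.7), and macrophage (91.3 on length, 96.9 on GC content), conduction (91.4, 88.3), neuron (28.7, 37.4) and endocardial genes (96.1, 87.8) on both. Sarcomere genes failed on length (16.7), as did cell cycle regulators (90.6) and fatty acid oxidation (97.1).

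**Figure D3:**
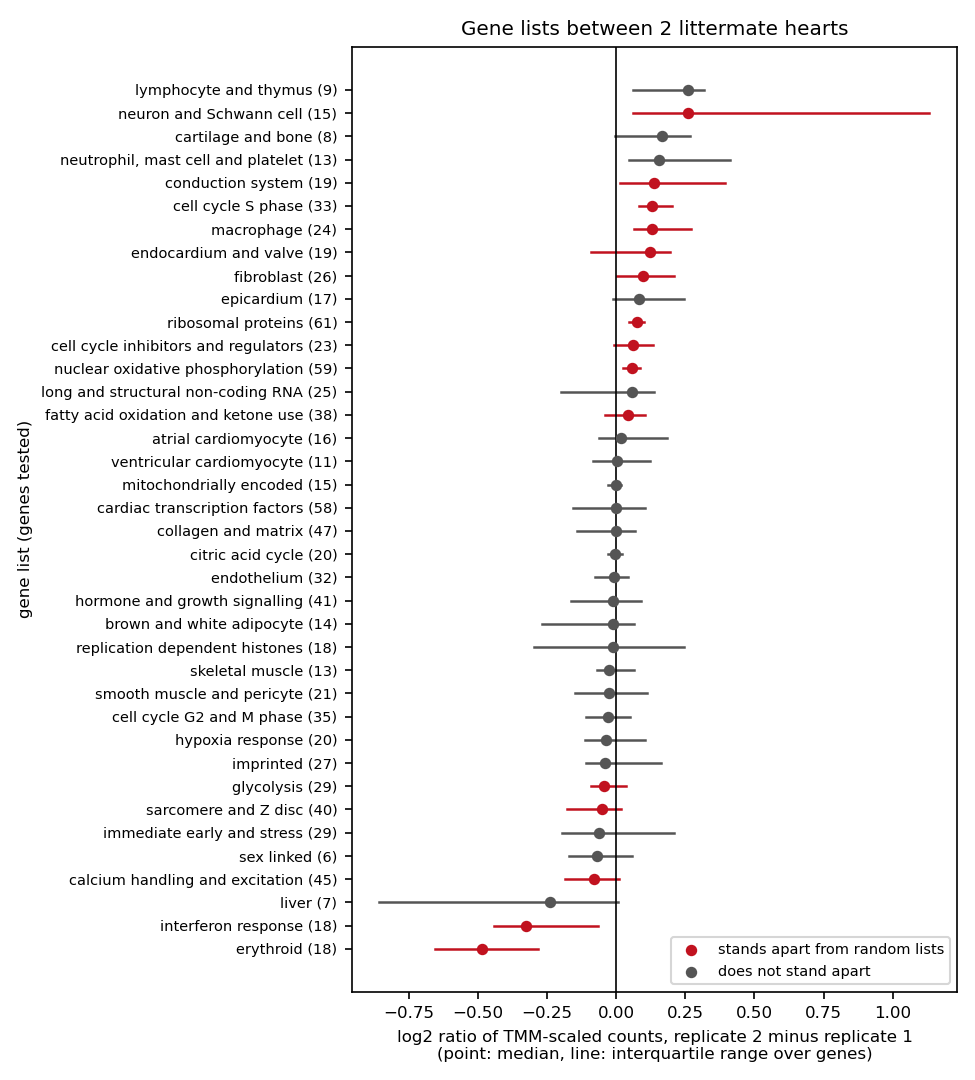
Median log2 ratio of TMM-scaled counts, replicate 2 minus replicate 1 (point), with the interquartile range over genes (line), for 38 of the 39 gene lists with 5 or more genes tested. The number of genes tested is in parentheses, lung epithelium is left out because its median of 1.70 lies off the scale, and the erythroid and interferon response lists lie farthest below 0.

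The largest single-gene differences were in genes of airway epithelium, high in replicate 2 and nearly absent from replicate 1. Scgb3a2, a secretoglobin of airway secretory cells (ENSMUSG00000038791.10, chromosome 18, 43764289 to 43767399), had 51 counts (2.96 TPM) in replicate 1 and 9592 (563 TPM) in replicate 2. Scgb3a1 had 23 and 3407 counts, Scgb1a1, the club cell secretoglobin, 14 and 1057, and Reg3g, an antimicrobial lectin gene, 5 and 3455. Cyp2f2 (log2 ratio 7.17), Agr2 (6.79), Muc5b (6.74), Tspan1 (5.17) and Sec14l3 (4.79) were also higher, as was the gene AU040972 (5.45). The opposite held for Sftpc, the surfactant gene of alveolar type II cells (chromosome 14, 70520949 to 70524081), with 685 counts (25.5 TPM) in replicate 1 and 9 (0.34 TPM) in replicate 2. Ager, a marker of alveolar type I cells, had 75 and 33 counts. The lung epithelium list therefore went both ways, with 7 of 11 genes higher in replicate 2 and a median of 1.70 (percentile 100). That median became 0.05 (percentile 76.4), no longer apart, with a mean count of at least 100.

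Nppb, induced by wall stress, was the most abundant of the genes counted as differing that were lower in replicate 2, at 360 TPM in replicate 1 and 143 TPM in replicate 2 (log2 ratio -1.32). Atf3, a stress-induced transcription factor gene, was lower by a similar step (10.6 and 4.15 TPM, log2 ratio -1.33), as were Nkd2 (-1.37) and Zbtb16 (-1.35). Outside the airway genes, those higher in replicate 2 included Angptl4, an inhibitor of lipoprotein lipase (44.9 and 93.4 TPM, log2 ratio 1.09), Spp1 or osteopontin (8.51 and 26.3 TPM, 1.63), Mmp12 (1.68), Car3 (1.99) and Shox2, a sinoatrial transcription factor gene (1.70 and 4.21 TPM, 1.09). These examples beyond the 10 most extreme in each direction were picked after their values were seen.

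In all, 45 genes were at least 2-fold higher and 22 at least 2-fold lower in replicate 2, of 13463 with a mean count of 50 or more. Of these 67 genes, 21 had shared reads, among them Rpl7a-ps11 (256 counts in replicate 2 and 0 in replicate 1), Gm8226 and Gm14308, and their differences are uncertain. Without shared-read genes, a restriction chosen after the data were seen, 34 were higher and 12 lower. Of the other genes with the most negative ratios, Gm27021 and Gm7336 also had shared reads, whereas Xlr3b (202 and 54.5 counts) did not. With 1 animal on each side these differences have no replicate check.

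**Figure D4:**
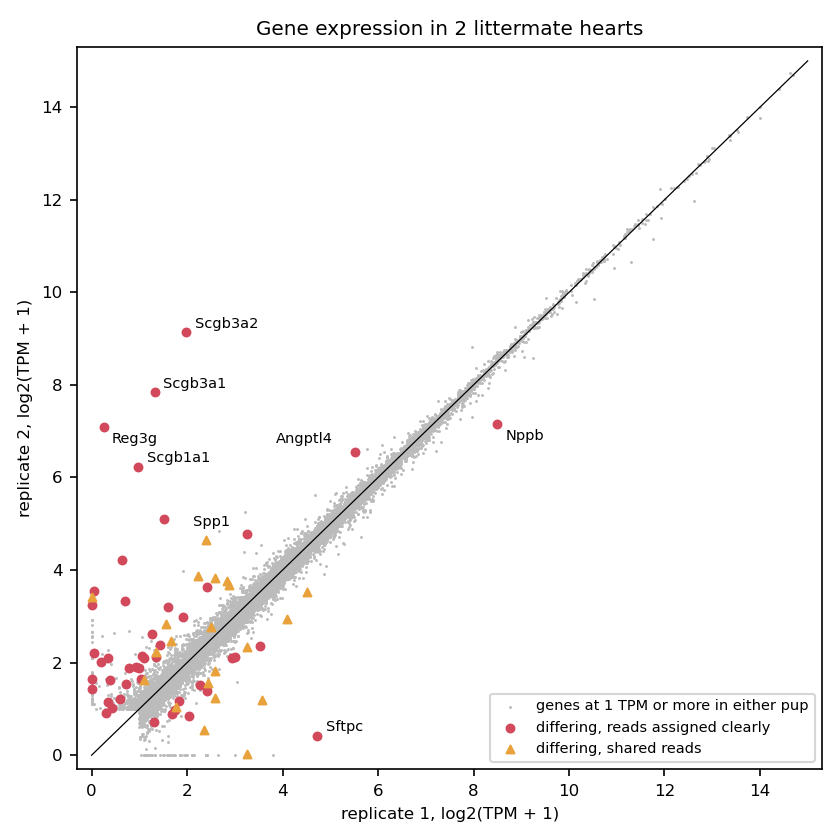
Expression of genes at 1 TPM or more in either pup, as log2(TPM + 1) in replicate 1 (horizontal axis) and replicate 2 (vertical axis). Circles mark differing genes with clearly assigned reads, triangles differing genes with shared reads, grey points all genes, and the line equal values; Scgb3a2 (2.96 and 563 TPM) lies far above the line and Sftpc (25.5 and 0.34 TPM) below it.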

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

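The tests on alveolar markers, low ciliated cell markers, shared reads, whole blood and haemoglobin copies were chosen only after the result was seen. Matching on length or GC content was written down before its percentiles were seen, but after the medians of the lists and a rough trend with length had been noticed. The requirement that such a percentile pass its limit by more than the spread of the list's median was put into the analysis after the percentiles were seen. No biological explanation was tested, since the samples form 1 group.

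Features named by a number held 36 counts in replicate 1 and 39 in replicate 2, above the 3 counts that a count of 0 allows. Feature 11364 took 30 and 33 of them.

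Secretory airway markers summed to 13.3 TPM in replicate 1 and 1097 TPM in replicate 2, which describes the pattern and does not test it, since the set was put together after 14 of its 18 measurable members had been counted as differing. RNA of alveolar lung in replicate 2 would raise alveolar markers, but the summed TPM of 12 had a log2 ratio of -1.58, mostly through Sftpc. Sftpc was known to be lower when this test was chosen, so that sum cannot decide. Without Sftpc the ratio was -0.29, and 9 of 11 markers were lower in replicate 2, Sftpd (15 and 66 counts) being an exception. Of the markers outside the fixed lists, Slc34a2 (-3.41), Lyz1 (-1.45), Napsa (-0.68), Rtkn2 (-0.08) and Etv5 (-0.04) were lower and Akap5 (0.14) higher. No rise of alveolar RNA was thus seen in these markers. Reads shared between paralogs are argued against by a largest uncertainty of the replicate 2 counts of 0.0510% over the 14 markers. RNA from airway epithelium may be a source, but the test written beforehand did not decide: over 19 ciliated and basal cell markers the median was 0.53, short of the bound of 1 set for it and just above the 0.5 set against it. Of the 19, 18 were higher in replicate 2 and 8 had a log2 ratio of 1 or more. Over all measurable members of each set, ciliated cell markers had a median of 1.89 (14 of 14 higher) and basal cell markers 0.24 (6 of 7). Ciliated cell markers under 2 TPM, set apart afterwards because abundant heart genes such as Mlf1 (463 and 511 TPM) could hide a small share, had a median of 2.48, but 10 of these 11 had been read in the first test and Foxj1 before it, so airway RNA stays open.

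Ribosomal protein and oxidative phosphorylation lists were higher and calcium handling genes lower in replicate 2, while the ratio of single genes followed effective length (rho -0.197) more than mean count (-0.0770) or GC content (0.0110). Among random lists matched on mean TPM and length, oxidative phosphorylation no longer stood apart (percentile 70.6). Its median of 0.06 was unchanged and that of the random lists moved from 0.01 to 0.05. With mean TPM and GC content matched, the median of the random lists was 0.04. Length may account for the loss, but so may the change from bins of mean count to bins of mean TPM. Random lists left out only the genes of the list tested. For oxidative phosphorylation they could hold ribosomal protein genes and unlisted complex I genes such as Ndufc1 and Ndufab1. Those for ribosomal proteins could in turn hold oxidative phosphorylation genes. Length and gene class therefore cannot be told apart by this matching. By the bound written beforehand, ribosomal proteins (percentile 97.98) and calcium handling (0.22) still stood apart after matching on length, as oxidative phosphorylation did on GC content (97.59), which would count against these causes. With medians moved 1 bootstrap SD nearer to the random lists, these became 72.2, 5.40 and 77.2, so by that later requirement all 3 are left open, calcium handling (median -0.08, against -0.02 in length-matched lists) by a narrow margin. GC content is argued against for ribosomal proteins (percentile 99.99) and calcium handling (0.02), which stayed outside the limits either way.

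Erythroid genes were lower in replicate 2, with a median log2 ratio of -0.48 over 18 genes. Less whole blood in that heart would lower neutrophil and platelet markers too, but 7 of these had a median of 0.0481 and a lower quartile of 0.0134. As a set they did not fall with the red cell genes. All belong to a fixed list whose median (0.15) was already known when this test was chosen, and Ltf is also a secretory airway marker. The values thus describe these genes and cannot decide on less whole blood as a fresh test would. Reads moved between haemoglobin copies are argued against by the sum over all copies, with a log2 ratio of -0.64. A different share of red cells or their precursors between the pups was not tested.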

How the results depend on the processing

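Leaving out nuclear mitochondrial copies or genes with shared reads was chosen only after the data were seen. Genes detected in both pups ranged from 8792 at 5 TPM to 17527 at 0.1 TPM, and were 13121 and 13162 in replicates 1 and 2 alone. The share in the 10, 50 and 100 most abundant genes moved to 13.6%, 30.3% and 39.9% over nuclear genes without small RNAs, to 12.7%, 26.1% and 33.2% on counts, and to 11.1%, 27.0% and 36.7% without nuclear mitochondrial copies, which by construction takes abundant genes out of the total. Pearson's r was 0.973 with a pseudocount of 0.1, 0.996 with no filter, 0.990 on FPKM and 0.994 on posterior means. The biological coefficient of variation was 0.0898 with DESeq2 size factors, 0.102 with no filter and 0.0941 at a mean count of 100 or more. Genes counted as differing numbered 277 higher and 145 lower at a mean count of 10, 18 and 12 at 200, 29 and 10 on TPM ratios, and 12 lower without shared-read genes. The main transcript was the same in 92.3% of genes at 1 TPM and 96.1% at 20 TPM. At 10 counts or more, 6 spike-ins were seen in both libraries. Eno3 over Eno1 reversed on counts not scaled by length (-0.0714), where the longer Eno1 weighs more. The lung epithelium list lost its shift with no filter on low counts (0.0129, percentile 47.2). At a mean count of 100 or more, sarcomere (percentile 3.08), conduction (97.05), neuron (94.9), lung epithelium (76.4) and fatty acid oxidation (97.1) lists no longer stood apart, while adipocyte (0.56), immediate early (1.93), epicardium (97.8) and histone (99.2) lists did. On TPM ratios conduction (97.4) and fatty acid oxidation (96.3) were lost, and epicardium (99.9), lymphocyte (97.8) and neutrophil (99.4) gained. With no filter cell cycle regulators (97.2) were lost, and liver (0) and immediate early (0.46) gained. Except where a sentence gives it, the cause was not tested. A single scaling factor per library cannot change a list's percentile and so says nothing of its stability.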

Other observations

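The examples in this part were chosen after their values were seen. Several abundant genes lay outside all lists. Usmg5, a small subunit associated with ATP synthase, stood at 4795 ± 124 TPM, and the ferritin heavy chain gene Fth1 at 2558 and 2655 TPM in replicates 1 and 2. Ppia, or cyclophilin A, stood at 2787 and 2850 TPM, and the complex I genes Ndufc1 and Ndufab1 at 2456 and 2584 TPM and at 2266 and 2382 TPM. Among non-coding genes outside the lists, Gm42418 (chromosome 17, 39846958 to 39848788) had 2804 and 2810 TPM. Hand2os1, transcribed beside the cardiac transcription factor gene Hand2, stood at 146 and 130 TPM, whereas Hand2 itself stood at 9.38 and 7.79 TPM. Their annotated spans overlap on chromosome 8, so with the use of strand not stated the division between them is uncertain.

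Single chamber genes had ratios on either side of 0, and the atrial and ventricular lists did not stand apart. Of those given here only Nppb, at -1.32, differed by as much as 2-fold. Myl7 and Sln, both atrial, each had a log2 ratio of 0.36, replicate 2 minus replicate 1, and Myl4 one of 0.22. Myh7 (-0.66), the ventricular transcription factor gene Irx4 (-0.33) and the stress-responsive gene Ankrd1 (-0.43) were lower in replicate 2, as was Myh6 (-0.31), which is expressed in both chambers. Nppa (-0.06) and the ventricular genes Myl2 (0.004) and Myl3 (-0.008) were nearly equal, and Gpx3 (0.21), also of the ventricular list, was higher. These values have 1 animal on each side.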
